A study of Deinococcus deserti with 4 samples.

How the data were processed

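RNA of Deinococcus deserti RD19 was sequenced from 1 culture divided into a non-irradiated and an irradiated part, each with and without Terminator exonuclease (TEX), which gave 4 groups of 1 library. The libraries with and without TEX came from the same RNA preparations and are not biological replicates. Per the labels' protocols, total RNA was poly(A)-tailed, treated with tobacco acid pyrophosphatase, ligated to a 5′ adapter, copied from an oligo(dT) primer, amplified and size-selected before sequencing on a HiSeq instrument. A fragmentation step and removal of rRNA are not given in the sources used here. Of 12 rRNA features, 7 had 0 sense reads in both libraries. Amplified reads carry no molecular identifiers, so copies of 1 molecule cannot be told apart. The intervals cover counting error only, treat reads as independent and can therefore be too narrow.

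The authors deposited raw counts of sense and antisense reads for 3633 annotated features in NI and IR, and counts of reads at 1883 gene start sites and 720 usable orphan start sites in NI_TEX and IR_TEX. The authors also deposited a comparison of IR with NI that gives, per the file headers, a fold change as a ratio, its log2 value, and a p-value with its adjusted form. It lists 11 genes at a fold of 0. SAMtools 0.1.8 and DESeq, its version not stated, are named per the submitters' processing notes, with no role. The aligner, the counting tool, the treatment of reads with several matches, the genome build, the window counted at a start site and the way sites were chosen are not given in the sources used here. Coordinates are those of the deposited files, counted from 1. Names came from the files and from a RefSeq gene table (ASM2068v1), which matched 3485 of 3633 locus tags. Of all features, 3095 had identical start and end in that table.

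Reads of IR were divided by those of NI, and IR_TEX by NI_TEX, after scaling by the median of ratios over all features with reads in both, a factor of 0.763 for genes and 0.963 for gene start sites. Orphan sites used the factor of the gene start sites. Each ratio has an exact 95% (Clopper-Pearson) binomial interval. A feature was listed as higher or lower when both libraries together had at least 100 reads, the ratio was at least 2 or at most its inverse, and the interval excluded 1. No p-value was computed, because each group held 1 library. Left out were 2 orphan entries with no position, 1 orphan site and 1 gene start site with a missing count. Of the 2990 measured features, 829 overlap another feature, and how their shared reads were counted is not given in the sources used here. The antisense counts enter only the closing section. The number of per-sample columns left unused was 0.

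The named genes were chosen by a rule fixed before the data were examined: the 15 highest and 10 lowest listed genes, every measured member of the radiation response and translesion lists, up to 4 members with the largest ratios of any other list, the 10 highest and 5 lowest gene start sites, and the 3 highest and 2 lowest orphan sites. For ranking genes and sites, any count below 3 reads in a library was set to 3. The Y-family polymerase gene and genes listed where fewer than 6 members passed were named after their values were seen. The 19 gene lists were fixed before the data were examined, with members matched by symbol, copy suffixes included, or by product text. The reading of symbols inside product text, and the removal of products that only name a family, a domain or another enzyme, were set after values had been seen. Each list median was placed among the medians of 10000 random lists matched on size and on 10 bins of mean count. The random lists did not keep neighbouring genes together. Bootstrap intervals used 10000 draws.

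The scaling and the listing rule were tested on simulated counts without biological spread, in which 200 features were changed, as many up as down. The simulated gene factor was the ratio of totals, 1.039, and was recovered as 1.037. In the data the median of ratios gave 0.763 and total counts 1.039. The simulation therefore did not test the choice between those scalings under unbalanced changes. For 3633 simulated genes the intervals held the true value in 94.83% of cases, 58.3% of the 2-fold and 100.0% of the 4-fold changes were listed in the right direction, and 0.0% of unchanged genes were listed. For 1882 simulated start sites the intervals held the true value in 96.23%, and 56.2% of 2-fold changes were listed. Alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3), total counts, minimums of 20 reads and none, a 4-fold ratio, an interval excluding 2-fold, protein-coding genes alone, and other limits for leaderless sites. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.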

Results

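The data came from Deinococcus deserti RD19, a streptomycin-resistant derivative of the desert isolate VCD115, a bacterium that survives doses of ionizing radiation lethal to most cells. A single exponential culture was divided into 2 parts. The irradiated part received 1 kGy of gamma rays at 23 Gy/min and recovered for 30 min, and the other part was handled alike without irradiation. From each part, RNA was sequenced without (NI and IR) and with (NI_TEX and IR_TEX) Terminator exonuclease, an enzyme that degrades RNA with a 5′ monophosphate and so enriches the triphosphate ends made at transcription start sites. Each of the 4 groups held 1 library, so no difference has a replicate check, and the intervals given are exact 95% intervals that cover counting error only. The sense reads on 3633 annotated features summed to 2120270 in NI and 2203370 in IR. Reads at the 1883 gene start sites summed to 867966 in NI_TEX and 996507 in IR_TEX, and those at 720 orphan sites, which the authors tied to no annotated gene, to 427210 and 1029170.

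The first comparison asked which transcripts differed after irradiation. The highest ratio of all listed genes was that of ddrA, a gene of the known radiation response for a protein that binds single-stranded DNA (Deide_09150, chromosome, 1114671 to 1115276, minus strand). Its reads numbered 331 in NI and 41823 in IR, 166-fold higher after scaling (interval 149 to 185). Among other genes of that response, ddrC (Deide_23280, chromosome, 2786977 to 2787675) was 119-fold higher (103 to 137), ddrD (Deide_01160) 49.7-fold (40.2 to 62.3), ddrB (Deide_02990) 34.6-fold (30.3 to 39.7), and ruvB, encoding the helicase that moves Holliday junctions (Deide_18350), 25.1-fold (22.3 to 28.5). Of 2990 features with at least 100 reads in both libraries together, 380 were listed as higher in IR and 101 as lower by the rule of a 2-fold ratio with an interval excluding 1. At a ratio of at least 4, 140 were higher and 7 lower.

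Of the 23 measured members of the list of the DdrO regulon and radiation response, 20 were higher, 0 were lower and 3 were neither. Their median log2 ratio was 3.16, above the medians of all 10000 random lists of the same size and expression. This list came from earlier work on Deinococcus, which includes this species, and is not independent evidence of its own direction. The gene for PprA, a DNA repair protein of this genus (Deide_2p01380), had a log2 ratio of 3.78 (3.63 to 3.93), and ddrOP3, a copy of the gene for the repressor DdrO on plasmid3 (Deide_3p02170), 4.51 (4.23 to 4.81). The gene for single-stranded DNA-binding protein, ssb, had a log2 ratio of 3.16 and gyrB, for a subunit of DNA gyrase, 3.41. The other gyrase gene, gyrA, reached 1.74. The 3 recA genes, for the recombinase of homologous repair, lay at 3.33 (chromosome, Deide_19450), 3.31 (plasmid1, Deide_1p01260) and 3.67 (plasmid3, Deide_3p00210). How reads shared between such copies were counted is not given in the sources used here, so the values of single recA and uvrA copies are uncertain.

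The nucleotide excision repair genes uvrB, at a log2 ratio of 2.82, and uvrA, at 1.60 for the chromosomal copy and 1.40 for the plasmid2 copy (Deide_2p02060), were also higher, with uvrD at 1.30. The helicase gene recQ was at 2.52 (Deide_11320) and its plasmid1 relative Deide_1p01280 at 1.89. The CinA-like gene Deide_19430, which lies upstream of the chromosomal recA, was at 2.74. The 3 members that met neither rule were mutS at 0.10 (-0.04 to 0.24), the gene for IrrE, the protease that cleaves DdrO (Deide_03030), at -0.18 (-0.40 to 0.04), and hutU at -0.72 (-0.87 to -0.57).

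On plasmid1, the repressor gene lexA (Deide_1p01870) went from 69 to 565 reads, a log2 ratio of 3.42 (3.06 to 3.81), and dnaE2, for an error-prone DNA polymerase (Deide_1p01900), from 170 to 890 reads, a log2 ratio of 2.78 (2.54 to 3.02). The start site of this lexA had 1 read in NI_TEX and 3 in IR_TEX, too few to compare. The chromosomal LexA repressor gene Deide_01180 had a log2 ratio of 0.38 (0.16 to 0.61) and was not listed by gene reads, while its start site went from 151 to 321 reads, a log2 ratio of 1.14 (0.86 to 1.43), and was listed as higher. These 3 genes made up the measured part of the translesion list, with a median of 2.78 at percentile 99.97 of random lists. Of these, lexA and dnaE2 lie close together on the same strand, which the random lists do not mirror. With all matches kept, 1.58 was the median, and the removal of matches was set after values had been seen. The authors' deposited table also held the Y-family polymerase gene between them, Deide_1p01880, at a fold of 12 with an adjusted p of 1.45e-3.

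Other genes of DNA repair and recombination moved less. Of 24 measured, 3 were higher and 21 were neither, with a median log2 ratio of 0.40 at percentile 99.55. Scaling by total counts turned that median to -0.042, with 2 higher and 1 lower. Those listed were nth, for endonuclease III, at 1.77, ung, for uracil-DNA glycosylase, at 1.49, and recD2 at 1.01. Of 9 DNA replication genes, dnaE2, shared with the translesion list, was the only one listed, and the median was 0.33 (percentile 83.3; -0.12 by total counts).

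Among the 15 highest genes, several had no assigned function. Deide_01090, annotated as a DinB family protein (chromosome, 117725 to 118210), went from 11 to 1215 reads, a log2 ratio of 7.18 (6.33 to 8.18). Its start site had 0 reads in NI_TEX and 2 in IR_TEX, too few to compare. Deide_09148 (1114582 to 1114674), which lies directly after ddrA on the same strand and overlaps only its last bases, went from 16 to 1643 reads (7.07). How reads running from ddrA into it were counted is not given in the sources used here, so its value is uncertain. Deide_04721 was at 6.48 (6.20 to 6.77), Deide_11446 at 4.45, Deide_19490 at 4.44, Deide_2p00980 at 4.16, Deide_05260 at 4.12, Deide_20580 at 4.08 and the Bug family gene Deide_15340 at 3.97. Proteins annotated as hypothetical or of unknown function made up 39.2% of the features listed as higher, 22.8% of those listed as lower and 29.5% of all measured.

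**Figure D1:**
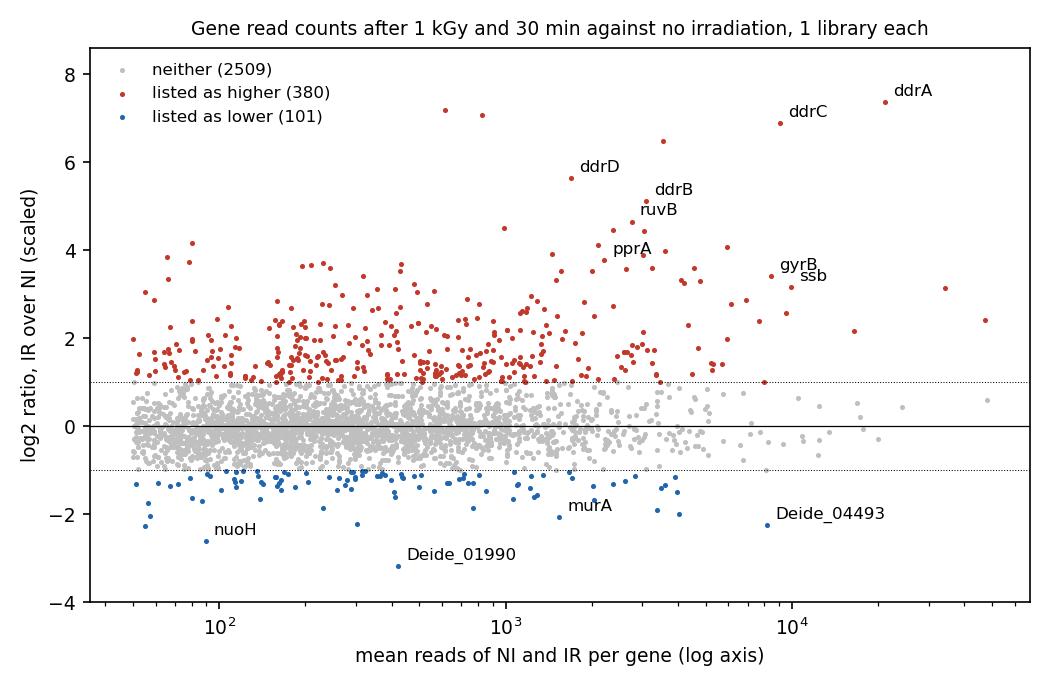
Each point is 1 of the measured genes, with the mean reads of NI and IR on a log axis and the scaled log2 ratio of IR over NI on the vertical axis. Red points are the 380 genes listed as higher and blue points the 101 listed as lower, dotted lines mark a 2-fold ratio, and ddrA lies at 7.37.

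nuoH, for a membrane subunit of NADH dehydrogenase (Deide_05160), went from 159 to 20 reads, a log2 ratio of -2.60 (-3.35 to -1.92), and nuoL, nuoF and the subunit M gene Deide_05210 were at -1.62, -1.13 and -2.04. Of 8 measured genes of the NADH dehydrogenase list, 4 were lower and 0 higher, and the median of -1.06 lay below all 10000 random medians. The 8 ATP synthase genes had a median of -0.45 (percentile 1.02), with Deide_00930 at -1.05 the only one listed, atpB at -0.91 and atpI at -0.80. The start site of Deide_00930 had 9530 reads in NI_TEX and 6640 in IR_TEX. That log2 ratio of -0.47 (-0.51 to -0.42) did not meet the 2-fold rule. The genes from nuoE to nuoK lie side by side on the same strand, and the ATP synthase genes named here also lie close together. Random lists draw scattered genes, so the percentiles of such linked lists can be too extreme. In the TCA cycle list, sdhB at -1.15 and Deide_12440 at -1.01, both for subunits of succinate dehydrogenase, were lower, while the list median was -0.04 (percentile 35.9).

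The lowest ratio of all listed genes was that of Deide_01990, a hypothetical gene (chromosome, 220963 to 221457), from 779 to 66 reads, -3.17 (-3.56 to -2.81). murA, for the enzyme of the committed step of peptidoglycan synthesis (Deide_18010), was at -2.07 (-2.21 to -1.92), and its neighbour Deide_18000 at -1.98. The abundant Deide_04493 went from 14073 to 2268 reads (-2.24), the DSBA oxidoreductase gene Deide_06420 was at -2.22, the siderophore transporter gene Deide_2p00400 at -2.27 and Deide_11206 at -1.89. Of 158 measured ABC transporter genes, 10 were higher, led by the permease gene Deide_08010 at 3.70, and 19 were lower. Their median was -0.20, below all 10000 random medians. By total counts 5 were higher and 56 lower.

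Of 53 ribosomal protein genes, 2 were higher and 2 lower, with a median of -0.13 (percentile 2.9), and by total counts 2 were higher and 8 lower. Those higher by the median of ratios were rplI at 3.60 and rpsR at 3.57, which directly follow ssb, and those lower were rplM at -1.12 and rpmI at -1.12. The aminoacyl-tRNA synthetases had a median of -0.25 (percentile 0.71), with proS at 1.02 the only 1 of 24 listed. Of 47 measured rRNA and tRNA genes, taken as a sign of RNA quality and removal, 17 were higher and 1 lower, with a median of 0.70 (percentile 99.99). By total counts 8 were higher and 1 lower, with a median of 0.26. Examples were trnE at 2.40 (Deide_20545), trnL at 2.15 (Deide_20215) and trnT at 2.14 (Deide_02445), and the 1 lower was the 23S rRNA gene rrlA at -1.86 (Deide_01303). Of the 3 measured rRNA features, 1 was listed as higher, 1 as lower and 1 as neither. The counting of reads shared between rRNA copies is not given in the sources used here. The tRNA genes took 5.44% of sense reads in NI and 6.24% in IR, and rRNA genes 0.031% and 0.018%.

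The medians of the remaining lists lay within the middle 95% of random medians. Among chaperones and proteases 3 of 18 were higher, ftsH (Deide_23310) at 1.89, lon at 1.60 and the ClpA gene Deide_08490 at 1.20, and the median was 0.33 (percentile 88.5; -0.12 by total counts). The start site of this lon was at 0.52 (0.24 to 0.79), short of the 2-fold rule, while that of this ftsH was at 2.06. Of 11 genes of oxidative stress defence and metal homeostasis, dps, for a protein that binds DNA and iron, at 1.78 and msrB at 1.14 were higher, with a median of 0.27 (percentile 87.1; -0.18 by total counts). Cell division and chromosome segregation had 1 of 32 higher, the same ftsH, and a median of -0.12 (percentile 8.4), with minD at -0.98, and by total counts 1 was higher and 4 lower. Type IV pili and secretion had 2 of 18 lower, the genes for PilN (Deide_17610) and PilO (Deide_17620), at -1.14 and -1.12, and a median of -0.10 (percentile 17.9). The median was 0.15 for glycolysis and gluconeogenesis (11 genes, percentile 67.2; -0.29 by total counts), -0.03 for RNA polymerase and core factors (11 genes, percentile 40.3) and -0.04 for transposases (19 genes, percentile 41.7), with 1 listed among them, the transposase gene Deide_16851 at 1.21. The carotenoid genes crtB and crtI were at 0.45 and 0.21. These percentiles are a description of these libraries.

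**Figure D2:**
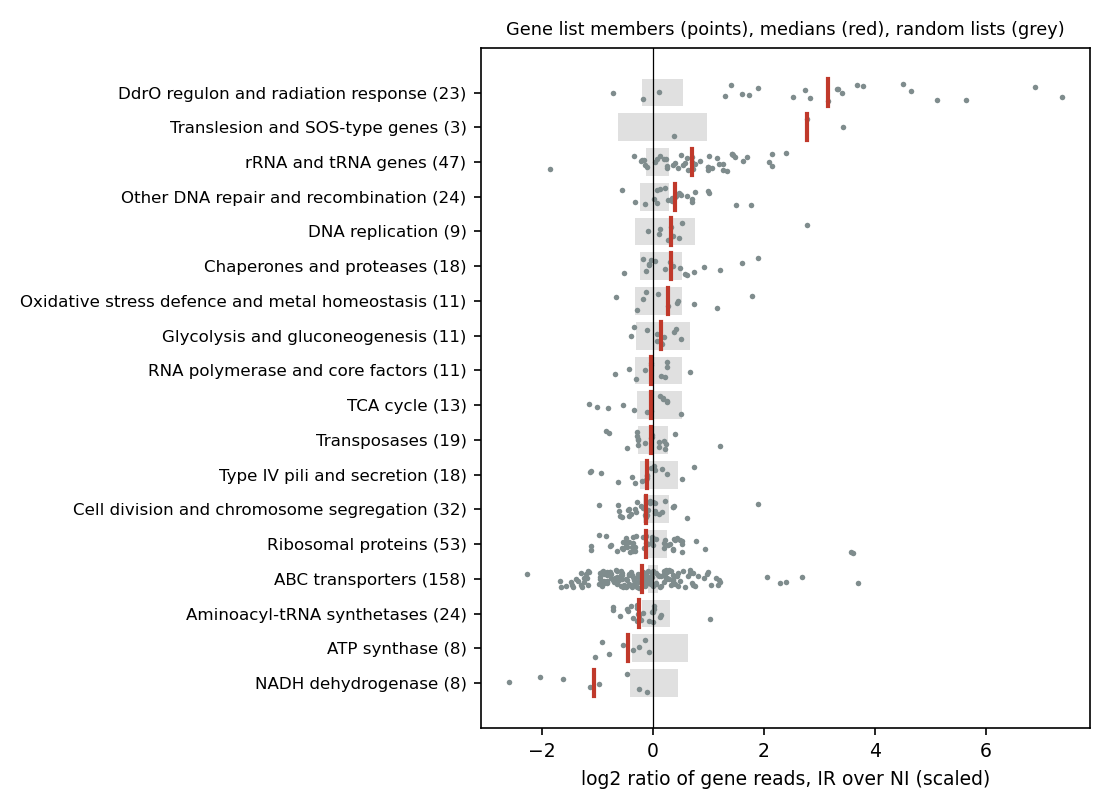
Each grey point is the log2 ratio of IR over NI of a measured list member, red bars are list medians, and grey bands hold the middle 95% of medians of 10000 random lists matched on size and mean count. The radiation response median of 3.16 and the NADH dehydrogenase median of -1.06 lie outside their bands.

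The direction of many smaller ratios depended on the scaling. Scaling by total counts shifts all gene log2 ratios by -0.45, and then 241 genes were higher and 361 lower, a share of 40.0% higher against 79.0% by the median of ratios. Among the lists, by total counts the radiation response had 18 higher and 1 lower, the aminoacyl-tRNA synthetases 0 and 3, NADH dehydrogenase 0 and 5, ATP synthase 0 and 3, the TCA cycle 0 and 3, and pili and secretion 0 and 4. Chaperones and proteases had 2 and 0, oxidative stress defence 1 and 1, transposases 0 and 2, and RNA polymerase and core factors 0 and 1. In the authors' deposited table, which compares these same 2 libraries, 40 of 3572 genes had an adjusted p below 0.05, of which 38 had a fold above 1 and 2, nuoH and Deide_01990, below it. In the authors' deposited table the adjusted p was 1.04e-7 for Deide_01090, at a fold of 145, and 1.00 for ddrA, at a fold of 166 and a p of 0.92. The authors' deposited table gave adjusted p values of 2.81e-3 for ddrD, 5.63e-2 for ddrB, 6.19e-2 for ruvB and 0.14 for ddrC, the last 3 above 0.05 at folds of 35, 25 and 119. Such a p compares libraries and not conditions. The 3559 genes with a ratio in both had log2 values within 0.02 of the authors' deposited table when scaled on the same genes.

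Start sites were compared to ask whether transcript 5′ ends changed alongside gene reads. The site of ddrA, on the first base of its start codon (chromosome, 1115276, minus strand), had 164 reads in NI_TEX and 24681 in IR_TEX, a log2 ratio of 7.29 (7.07 to 7.52). The sites of Deide_04721 and ddrC, both likewise at the start codon, were at 7.17 and 6.96, and that of ddrD at 6.17. The site of the plasmid1 recA, 57 nt upstream of the start codon, was at 5.51 (4.58 to 6.65) from 9 and 396 reads, and those of ddrB, Deide_18730, Deide_15340 and ruvB were at 5.16, 4.86, 4.80 and 4.62. Deide_13110 had a site ratio of 4.58 but a gene ratio of 0.49. The lowest sites were those of the M48 peptidase gene Deide_21060 at -2.92 (-3.51 to -2.38), murA at -2.85, Deide_18000 at -2.35, infA, for translation initiation factor IF-1, at -2.26, and Deide_06420 at -2.14. The gene reads of infA had a ratio of -0.27.

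Of 1412 gene start sites with at least 100 reads, 254 were listed as higher in IR_TEX and 58 as lower, 81.4% higher. Scaling by total counts, which shifts all site log2 ratios by -0.25, gave 199 and 118, or 62.8% higher, and by the totals of gene and orphan sites together, an alternative chosen after the data were seen, 140 and 424, or 24.8% higher. The combined total leans on few sites. A single orphan site, at 70257 on the chromosome, held 0.313% of all gene and orphan site reads in NI_TEX and 21.1% in IR_TEX.

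Across 1377 genes with at least 100 reads in both kinds of library, the gene and site log2 ratios had a Pearson r of 0.865 and a Spearman rho of 0.742. Genes are not independent replicates, and both kinds of library came from the same RNA. Of 252 genes listed by gene reads, 247 had a site ratio of the same sign. Both measures listed 202 genes, 179 as higher in both, among them ddrA, ddrC and ruvB, and 23 as lower in both, among them murA, and 0 were listed in opposite directions. These counts leave out conflicts where only the site was listed. The site of rplU was at 1.05 (0.77 to 1.33) with gene reads at -0.85, and that of Deide_2p00350 at 3.11 with gene reads at 0.01.

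**Figure D3:**
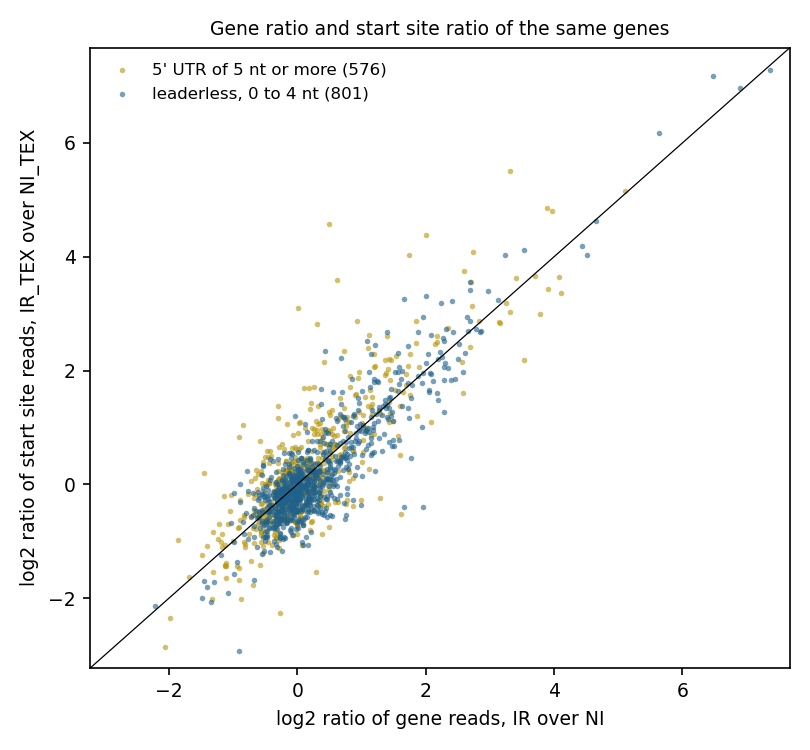
Each point is 1 of 1377 genes, with the log2 ratio of gene reads (IR over NI) on the horizontal axis and of start site reads (IR_TEX over NI_TEX) on the vertical axis. Blue points are leaderless genes, the line marks equal ratios, and the Pearson r is 0.865.

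Among orphan sites, the reads at 70257 on the minus strand of the chromosome, between Deide_00600 and Deide_00610, went from 4049 in NI_TEX to 428066 in IR_TEX, a log2 ratio of 6.78 (6.73 to 6.82). This site alone took 0.948% of orphan reads in NI_TEX and 41.6% in IR_TEX. The highest ratio was that of the site at 2787714 on the plus strand, between ddrC and Deide_23290 and pointing away from ddrC, with 2 and 832 reads (8.76, interval 6.90 to 11.80). A site 5 nt from it, at 2787709, had 3 and 247 reads (6.42, interval 4.85 to 8.71). The lowest were at 2632502 on the minus strand at -3.09 (-3.67 to -2.55) and at 513582 on the plus strand, 47 nt upstream of Deide_04493, at -2.43 (-2.63 to -2.24). Of 573 orphan sites with at least 100 reads, 72 were higher and 34 lower, 67.9% higher.

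Leaderless transcripts, which start at or next to the start codon and so lack a 5′ UTR with a ribosome binding site, are the subject of the study's title. Of 1883 gene start sites, 1114 lay 0 to 4 nt from the start codon, 59.2% (Clopper-Pearson interval 56.9 to 61.4), and 873 exactly on its first base, 46.4% (44.1 to 48.6). Leaderless sites made up 64.2% of sites on the chromosome (61.8 to 66.6), 36.4% on plasmid1, 39.6% on plasmid2 and 34.4% on plasmid3. Of 20 ribosomal protein genes with a site, 0 were leaderless (Clopper-Pearson upper limit 16.8%), and of 73 ABC transporter genes 25 were. Among 21 members of the radiation response list with a site, 10 were leaderless, including ddrA, ddrC, ddrD and ruvB. The other 769 gene start sites had a median 5′ UTR of 65.0 nt.

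**Figure D4:**
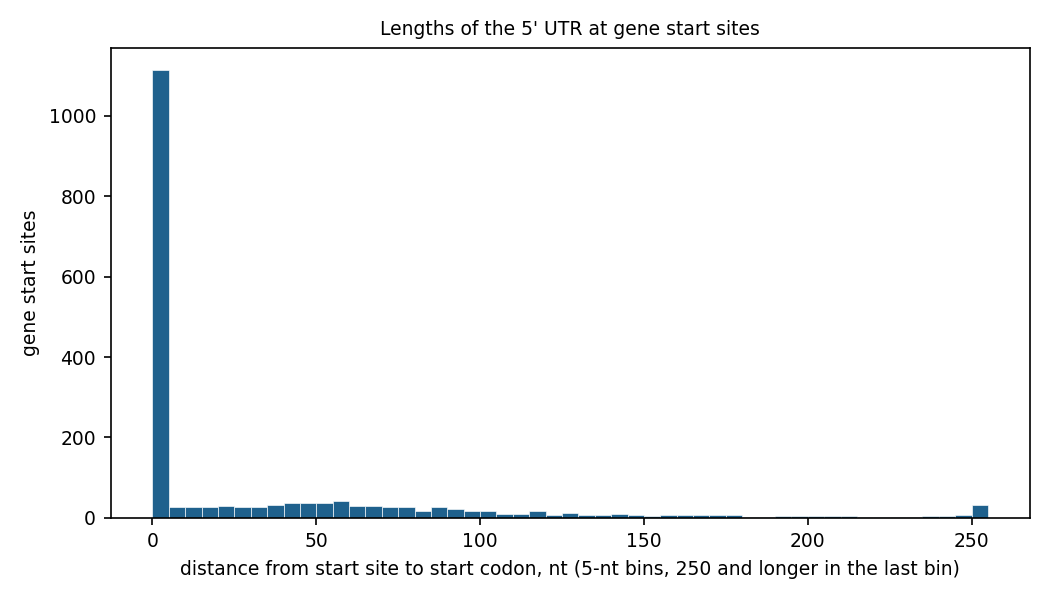
Distance from the start site to the start codon in nt, in bins of 5 nt, against the number of gene start sites. The first bin holds the 1114 leaderless sites of 0 to 4 nt.

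Whether the classes differed after irradiation was asked of both measures. By gene reads, the median log2 ratio was 0.07 for 1075 leaderless genes and 0.02 for 720 leadered genes, the leaderless median at percentile 95.7 of random lists. By site reads, it was -0.05 for 809 leaderless and 0.06 for 603 leadered sites, at percentile 3.25. With leaderless set to exactly 0 nt and with a minimum of 20 reads, the percentiles were 2.07 and 0.125 by site reads, both outside the middle 95% of random medians, and 96.5 and 86.8 by gene reads. The difference had opposite signs in the 2 measures. Genes listed as lower with a site were leaderless in 14 of 43 cases, 32.6% (19.1 to 48.5), and those listed as higher in 158 of 259, 61.0% (54.8 to 67.0). Of sites listed as lower, 23 of 58 were leaderless, 39.7% (27.0 to 53.4), of those listed as higher 135 of 254, 53.1% (46.8 to 59.4), and of those not listed 59.2%. Of reads at gene start sites, 32.2% in NI_TEX and 37.2% in IR_TEX fell on leaderless sites. A few sites carried most of that difference. Without the 10 sites with the highest ratios, an alternative chosen after the data were seen, the shares were 32.1% and 33.9%. The 5 leaderless sites among those 10, of ddrA, Deide_04721, ddrC, ddrD and ruvB, had 567 reads in NI_TEX and 50390 in IR_TEX.

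Replicon medians lay near 0, which for the chromosome follows from the scaling, as it holds 2403 of the 2990 measured features. The median log2 ratio was 0.01 for the chromosome (2403 genes, percentile 48.7), 0.07 for plasmid1 (202 genes, percentile 96.3), -0.08 for plasmid2 (181 genes, percentile 2.85) and 0.03 for plasmid3 (204 genes, percentile 89.8). By total counts, which shift every log2 ratio by the same -0.45, all 4 medians were below 0. plasmid1, which carries lexA and dnaE2, had 18.8% of its genes listed as higher, the chromosome, which carries ddrA to ddrD, 12.5%, plasmid2 11.0%, and plasmid3, which carries ddrOP3 and a recA gene, 10.3%.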

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

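Of the tests given here, those of wrong-strand counting, of tRNA, of the scaling factor and of the 15 highest genes were chosen after the result, or values bearing on it, had been seen. The test of convergent neighbours was written before its value was known, though an example, Deide_02980 beside ddrB, had been noticed.

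Antisense reads, which no comparison of the report uses, showed a signal. Of 1302 genes with at least 100 antisense reads, 51 had at least 2-fold more after irradiation and 16 at least 2-fold fewer, by the median of ratios of the gene reads. The antisense log2 ratio of the 51 had a median of 1.26. Total counts shift every such ratio by -0.45, so by that scaling most of the 51 would fall below 2-fold. Antisense reads made up 12.8% of sense and antisense reads together in NI and 10.1% in IR. Deide_02980, which faces ddrB tail to tail, had 109 antisense reads in NI and 2725 in IR, a log2 ratio of 5.03 (4.76 to 5.32), while its sense ratio was 0.04. Deide_3p02160, which faces ddrOP3, had 50 and 395, a log2 ratio of 3.37 (2.95 to 3.83).

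Counting of a fixed share of sense reads on the wrong strand is argued against: in the 7 genes that were at least 16-fold higher in sense and had at least 20 antisense reads, the median antisense log2 ratio was -0.22 (bootstrap interval -1.99 to 0.39), against a sense median of 5.11. Of the 45 genes among the 51 whose sense reads could be measured, 3 were listed as higher in sense, and their sense median was -0.14. Of the 51 genes, 16, or 31.4% (19.1 to 45.9), had a convergent neighbour at least 2-fold higher, against 4.40% of the other 1251 genes. This met the limit set beforehand for arguing against transcription running on from such a neighbour in most of the 51. Only 28 of the 51 had any annotated convergent neighbour, so the others could not count towards that limit. Meeting it therefore does not decide the question, and 31.4% was above the share of the other genes. The test covered only this cut, this scaling and annotated neighbours. The neighbours of tmk (Deide_16510) and Deide_06041 lay just below the cut, at log2 ratios of 0.962 and 0.945. Such transcription stays open for the 16 and is not settled for the rest. Changed antisense transcription of other origin after irradiation was not tested.

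More genes were at least 4-fold higher than lower after irradiation, and the choice among the scalings used is argued against as the whole cause. By total counts, the scaling that gave the fewest higher genes, 79 were higher and 20 lower, or 79.8% (70.5 to 87.2). That interval treats genes as independent, and a factor beyond those used was not tested. Whether a few strongly raised genes shift the total count cannot be told apart from a wider change. Without the 140 genes at least 4-fold higher, which held 4.07% of sense reads in NI and 24.0% in IR, the ratio of totals was 1.08 times the median of ratios, and without the 15 highest genes 1.29 times. The value of 1.08 met the limit of 10% set beforehand, but the 140 genes are not few and were picked by the same ratios, and neither value has a spread. An effect of irradiation stays open as untested, with 1 library per group.

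The tRNA genes had a median log2 ratio of 0.71 over 44 genes, of which 16 were listed as higher and 28 as neither. Its size depended on the scaling factor, but the choice among the scalings used is argued against as the whole cause: by total counts, which gave the lowest value, the median was 0.27 (bootstrap interval 0.065 to 0.56), with 8 higher. That interval resamples genes as if independent and holds no spread between cultures, and a factor beyond those used was not tested. Favoured recovery of short transcripts in IR cannot be told apart from a change of tRNA itself, because the 30 coding genes of at most 150 nt had a median of 0.20 with an interval of -0.10 to 0.74. Reads shared between tRNA copies were not tested.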

How the results depend on the processing

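The scalings by total counts of gene lists, named genes and replicons, the lists with all matches kept, the gene set without tRNA, rRNA and overlapped genes, the leaderless read shares without the 10 highest sites, and the totals of gene and orphan sites were chosen after seeing the data. No paired analysis was possible because each group held 1 library. The cause was not tested for any change below, apart from the stricter or looser rule itself. Total counts gave 241 higher and 361 lower genes, and 118 lower start sites. Totals of gene and orphan sites gave 140 higher and 424 lower start sites. A 4-fold ratio gave 140 higher and 7 lower genes, and 105 and 9 sites. An interval excluding 2-fold gave 46 lower genes and 28 lower sites. Without tRNA, rRNA and overlapped genes, 60 genes were lower. Minimums of 20 reads and none each gave 91 lower sites. Exactly 0 nt gave a leaderless share of 46.4%. The correlation of gene and site ratios was 0.942 at 1000 reads and 0.837 at 20.

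By total counts the median of other DNA repair genes turned from 0.40 to -0.042. Total counts moved those of DNA replication to -0.12, cell division to -0.57, chaperones to -0.12, ribosomal proteins to -0.58, tRNA synthetases to -0.70, glycolysis to -0.29, RNA polymerase to -0.48, transposases to -0.49, ABC transporters to -0.65, pili and secretion to -0.55, and rRNA and tRNA genes to 0.26. The replicons moved to -0.44 (chromosome), -0.38 (plasmid1), -0.53 (plasmid2) and -0.41 (plasmid3). Another 80 alternatives lay within 1.5 times the count, or within the interval of the share, correlation or median, TMM scaling among them. For short lists that interval is wide: it held oxidative stress defence at 0.27 and, by total counts, -0.18, ATP synthase at -0.45 and -0.90, the TCA cycle at -0.04 and -0.48, and the translesion list at 2.78 and, with all matches kept, 1.58. Depth limits the sites, with a median of 111 reads in NI_TEX and 122 in IR_TEX.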

Other observations

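These groups and genes were chosen after their values were seen. Of 11 measured N-acetyltransferase genes, 5 were listed as higher and 0 as lower, with Deide_14940 at a log2 ratio of 3.59, Deide_20140 at 3.53 and Deide_19920 at 2.69, and a median of 0.62 (percentile 99.0). By total counts 3 were higher and 1 lower, with a median of 0.17. Of 8 annotated leader peptides upstream of tRNA synthetase genes, 3 were higher, those of the tyrosine (Deide_00051, 1.99), methionine (Deide_09379, 1.33) and aspartate (Deide_10019, 1.26) enzymes. The gene metG for the methionine enzyme, named for its large ratio within its list, was at -0.59. Among 24 measured synthetase genes 1 was listed as higher, proS, and 0 as lower. The median of the 8 was 0.10 (percentile 60.7), and by total counts 1 was higher and the median -0.34.

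Next to ssb, at 3.16, the genes rpsR and rplI were at 3.57 and 3.60, while rpsF on its other side, for another ribosomal protein, was at 0.52 (0.38 to 0.67). The 2 pilus genes listed as lower stand in a row with pilM, at -0.95, and Deide_17630, at -0.94. Of the 6 orphan sites with the most reads, 3 were at least 8-fold higher in IR_TEX, at 70257, 2770723 (14821 to 116216 reads, 3.03) and 404774 (5793 to 55217 reads, 3.31) on the minus strand of the chromosome. The other 3 had log2 ratios of 0.03, -0.05 and -0.13.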
